A study of Heterostelium pallidum with 10 samples.

How the data were processed

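Gene expression was measured by sequencing polyA RNA of the social amoeba Heterostelium pallidum, strain PN500. Per the labels' protocols, cells fed on lawns of the bacterium Klebsiella planticola and were collected while food was still left, RNA came from frozen pellets, and libraries were made with an Illumina mRNA-Seq kit after capture of polyA RNA on oligo-dT beads. The 10 libraries fell into 5 groups of 2 by their titles: growing cells (0 h), cells starved for 2 h or 3 h, and cells starved for 2 h or 3 h with glorin. The labels do not say when glorin was added or how much. Each title also carries an experiment number, 1 or 2, which was used as the replicate number. Nothing in the labels says what separates the experiments, so p-values measure the spread between these libraries, which may be partly technical.

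The deposited values are RPKM (reads scaled by gene length and by sequencing depth), per the file headers. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Each file lists the same 12627 genes by identifier. The files do not pair identifiers with names, so genes are given by identifier and the 33 lists of genes by function that were fixed before the data were examined could not be used (0 matched). No more than 2 rising and 2 falling genes are named per comparison. No value equals 0.

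RPKM values of one gene moved in whole steps between libraries, and these steps gave a whole length and whole reads. A length was found for 100% of genes, and 100% of values were whole within 0.01 read. Of 500 genes with values shuffled between genes, 0% gave a length, and of 2000 simulated genes 100% gave the true length. Lengths ran from 51 to 22239 nucleotides (median 1161) and 98.51% were multiples of 3, so they are called coding lengths. Recovered reads exceeded the total used for scaling by 11784 to 12252 per library, close to 1 read for each listed gene. This is how the absence of 0 was read, as 1 read added to every gene before scaling, which is an inference from the values. Read numbers printed below have that read removed, and RPKM values are as deposited. The scaling totals ran from 16943246 to 24489837 reads per library. A single read was worth 0.0352 to 0.0508 RPKM at the median coding length, so differences below that level were not detectable at this depth.

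Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a trend) on log2(RPKM + 1). Genes with a mean of at least 1 RPKM over the 10 libraries were tested, 10222 in all. One model held the 5 group means and left 5 residual degrees of freedom. The average glorin difference over both times was fitted on the 8 starving libraries with time as a term. P-values are two-sided and Benjamini-Hochberg adjusted within each of 9 contrasts at 0.05. A log2 fold change is on the log2(RPKM + 1) scale and understates the change of low genes. Errors of levels are SD and errors of log2 fold changes are SE. The named genes were the largest rises and the largest falls of each contrast among genes that passed and whose libraries of the compared groups did not overlap. Where no gene passed, the 10 genes with the smallest unadjusted p qualified, and they are reported as not passing. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

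The experiment numbers pair the libraries. Deviations from the group means correlated across genes between all 10 pairs of groups, with r from 0.83 to 0.93 (mean 0.88). The pairing comes from the experiment number in the titles. The design fixed before the data were examined has no term for experiment, and the fit with experiment as a block (4 residual degrees of freedom) is printed beside each count that it moves. On simulated reads for glorin against no glorin at 2 h (10215 genes tested, dispersion 0.02), the fit without the block recovered 0% of genes changed 2-fold, 1.5% of those changed 4-fold and 22.7% of those changed 8-fold, with 0 false calls. With the block these shares were 67.2%, 95.5% and 97%, with 15 false calls. The simulation gave every group the same difference between experiments, and its dispersion was set and not estimated. It therefore favours the fit with the block.

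Alternatives fixed before the data were examined were other pseudocounts (0.1 and 5), no filter on low values, quantile normalization, median-ratio scaling of each library, the block, a fit on the compared groups alone, a 2-fold minimum, and leaving out each library in turn. Chosen after the data were examined were limma voom on recovered reads, the block together with voom or with median-ratio scaling, counts of genes that moved 2-fold in both experiments, counts of genes crossing from under 1 to at least 10 RPKM or back, overlaps after scaling, and correlations taken across experiments for contrasts that share a group. A planned count test on recovered reads was left out by choice, as the deposited unit is RPKM, and voom was run on those reads in its place.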

Results

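The response of a social amoeba to starvation and to glorin was measured in 10 RNA libraries. Glorin is the secreted small peptide-like signal that draws starving cells of this group of species together into aggregates. The comparison was between growing cells (0 h), cells starved for 2 h or 3 h, and cells starved for the same times with glorin, with 2 libraries per group, 1 from each of 2 experiments. Scaling totals ran from 16943246 reads (3 h with glorin, experiment 2) to 24489837 reads (growing, experiment 1). Between 801 and 1264 of the 12627 listed genes had no read in a given library.

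Starvation and the experiment were the main sources of spread. The first principal component held 59% of the variance and parted the experiments, and the second held 27.1% and parted growing from starving cells. Replicates of a group correlated across genes at r = 0.938 to 0.959, and 8 of the 10 libraries lay closest to a library of their own experiment. Averaged over the groups, the median gene was 0.72 higher in experiment 2 than in experiment 1 on the log2 scale (quartiles 0.32 and 1.15). The 100 genes with most reads held 43.4% to 50.1% of reads in experiment 1 and 31.5% to 36.8% in experiment 2.

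**Figure D1:**
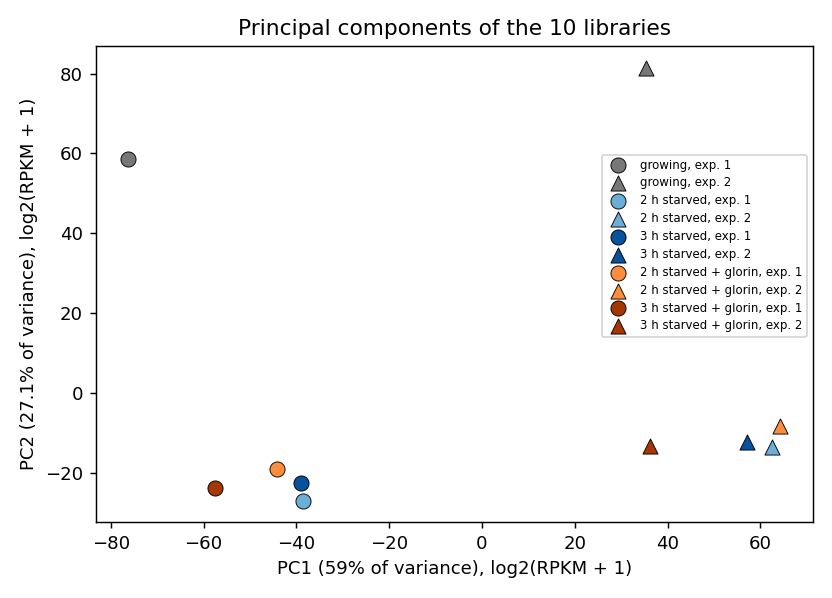
Scores of the 10 libraries on the first principal component (x axis, 59% of the variance) and the second (y axis, 27.1%) of log2(RPKM + 1), with 1 point per library, colour for the group, circles for experiment 1 and triangles for experiment 2. The experiments separate along x, and the growing libraries lie above the 8 starving libraries along y.

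The first question was which genes respond to removal of food. After 2 h of starvation 407 genes rose and 269 fell against growing cells. The gene PPL_02774 rose from 0.192 ± 0.033 to 284 ± 52.4 RPKM (SD, n = 2), a 1477-fold increase of the mean, and PPL_02780, a gene with a nearby number, rose from 0.248 ± 0.0211 to 277 ± 38.4 RPKM, 1115-fold. PPL_07847 fell from 420.5 ± 309 to 0.653 ± 0.219 RPKM, and PPL_09988 fell from 255 ± 282 to 2.52 ± 3.29 RPKM. In growing cells PPL_02774 was covered by 19 and 10 reads, and after 2 h by 26380 and 16665 reads.

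Log2 fold changes for the 2 h comparison were 7.89 ± 0.23 for PPL_02774 (limma, adjusted p = 1.1e-05) and 7.79 ± 0.21 for PPL_02780 (adjusted p = 1.1e-05). PPL_07847 changed by -7.78 ± 0.55 (adjusted p = 0.000506) and PPL_09988 by -5.93 ± 1.29 (adjusted p = 0.0413). Growing cells of experiment 1 and experiment 2 differed in their level of PPL_09988, with 56.1 and 454.7 RPKM, and its log2 fold change was -5.58 and -6.28 in them. After 2 h the gene was covered by 0 and 20 reads, so the size of the change in experiment 1 depends on the pseudocount. Its call ended with any library of the 2 groups left out (limma, adjusted p = 0.0591 without growing cells of experiment 1, 0.188 without those of experiment 2, 0.217 and 0.0983 without the 2 h library of experiment 1 and 2; log2 fold change -7.43, -4.44, -4.79 and -7.08) and with a pseudocount of 0.1 (log2 fold change -7.06, adjusted p = 0.0595). It held with quantile normalization (adjusted p = 0.00345), median-ratio scaling (adjusted p = 0.00321) and the block (adjusted p = 6e-07; limma). With the experiment as a block 4632 genes rose and 1780 fell, and with the block and median-ratio scaling 2491 rose and 3208 fell. Median-ratio scaling without the block gave 742 rises and 872 falls, and the median log2 fold change over all genes was 0.324 in the deposited values and -0.048 after scaling. Of all genes, 1187 were at least 2-fold higher and 586 at least 2-fold lower in both experiments, and 0 moved 2-fold in opposite directions. With 1 library of the compared groups left out the count of changed genes was 127 to 191.

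After 3 h of starvation 295 genes rose and 278 fell against growing cells. PPL_02774 stood at 371 ± 13.8 RPKM and PPL_02780 at 377 ± 15.2 RPKM (SD, n = 2), 1930-fold and 1520-fold above growing cells. PPL_07847 had fallen to 0.513 ± 0.411 RPKM. PPL_11723 fell from 115 ± 3.86 to 1.75 ± 0.573 RPKM, a 66-fold drop of the mean, with 14 and 23 reads left. At 2 h it stood between, at 6.66 ± 1.09 RPKM.

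The log2 fold changes at 3 h were 8.29 ± 0.23 for PPL_02774, 8.24 ± 0.21 for PPL_02780 (limma, adjusted p = 1.06e-05 for both), -7.92 ± 0.55 for PPL_07847 (adjusted p = 0.000533) and -5.42 ± 0.31 for PPL_11723 (adjusted p = 0.000291). The 2 h and 3 h changes from growing cells, taken from different experiments so that no library was shared, correlated across genes at r = 0.88 and 0.85. Both changes subtract the growing group, so whatever repeats in that group raises r even across experiments. Genes are not independent replicates. With the block 4338 genes rose and 1790 fell, and with block and median-ratio scaling 2438 rose and 2940 fell, the median log2 fold change over all genes being 0.295 before scaling and -0.016 after. In both experiments 922 genes were 2-fold higher and 562 were 2-fold lower, and 1 moved in opposite directions. Leaving out 1 library gave 140 to 197 changed genes.

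**Figure D2:**
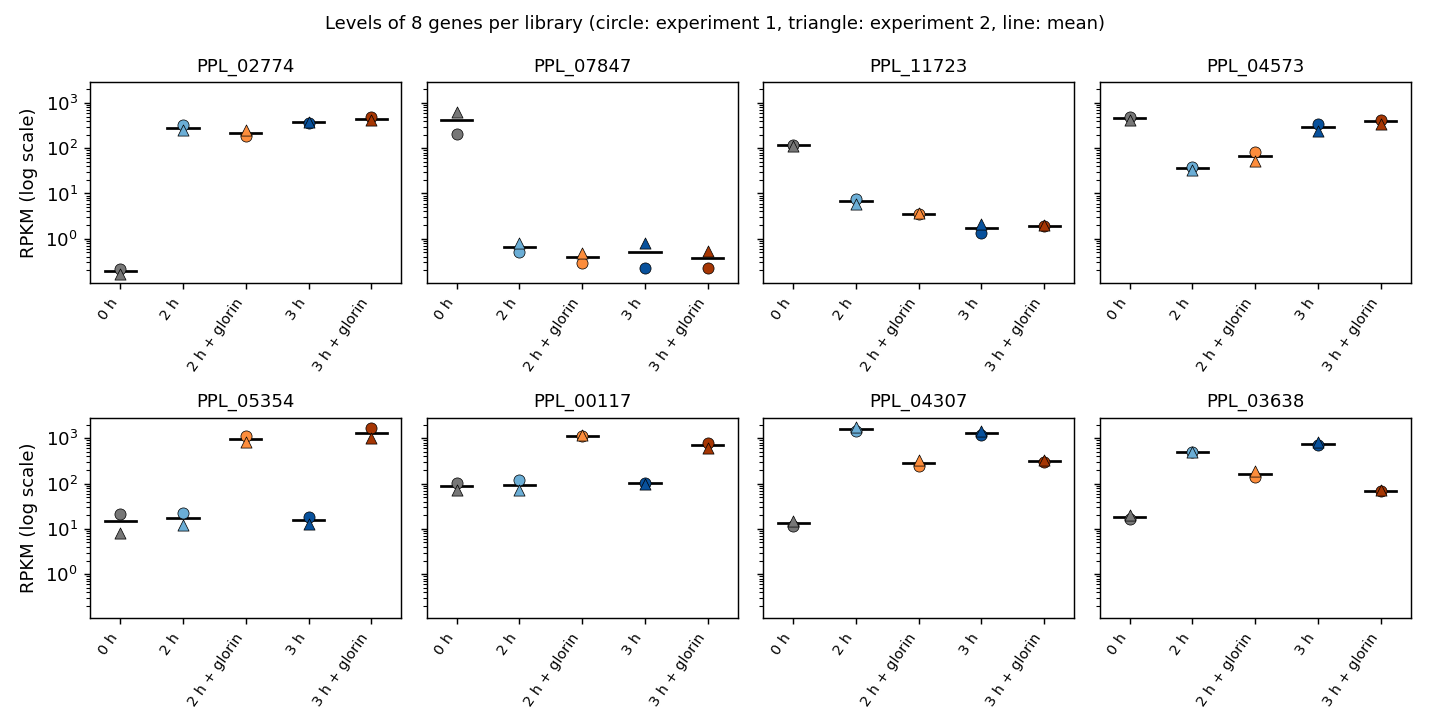
RPKM of 8 genes (y axis, log scale) in the 5 groups (x axis), with a circle for experiment 1, a triangle for experiment 2 and a line for the mean. The mean of PPL_02774 was 0.192 RPKM in growing cells and 218 to 450.5 RPKM in the starving groups, while that of PPL_05354 was 988 and 1336 RPKM in the groups with glorin and 14.6 to 17.4 RPKM in the others.

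Between 2 h and 3 h of starvation without glorin 1 gene was higher and 4 were lower in the fit without the block. In that fit 294 of 10222 genes had an unadjusted p under 0.05 (limma), less than the share of 0.05 due if no gene differed. It leaves the experiment difference in its error, so the small count says little about how many genes changed. PPL_04573 rose from 36.1 ± 4.07 to 293 ± 75.2 RPKM (SD, n = 2), 8.13-fold, and had been at 456 ± 49.4 RPKM in growing cells. PPL_07308 fell from 65.9 ± 0.201 to 6.54 ± 0.557 RPKM, a 10.1-fold drop, and PPL_00994 from 117 ± 2.96 to 19.8 ± 2.88 RPKM. The log2 fold changes were 2.97 ± 0.29 (limma, adjusted p = 0.0395), -3.15 ± 0.23 (adjusted p = 0.0215) and -2.52 ± 0.26 (adjusted p = 0.0451). With the block 283 genes rose and 506 fell, and with block and median-ratio scaling 408 rose and 450 fell. PPL_04573, PPL_07308 and PPL_00994 passed with the block (limma, adjusted p = 2.43e-06, 2.26e-06 and 1.58e-05). In both experiments 38 genes were 2-fold higher and 127 were 2-fold lower. No call was left after quantile normalization (0 genes) or with any library of these groups left out. Under quantile normalization the log2 fold changes stayed at 3.05 ± 0.52 for PPL_04573, -3.15 ± 0.45 for PPL_07308 and -2.48 ± 0.36 for PPL_00994. In the fits with a library left out, which break the pairing, they were 2.71 to 3.23, -3.23 to -3.08 and -2.66 to -2.38 in that order. Median-ratio scaling gave 8 genes, but the named genes PPL_04573, PPL_07308 and PPL_00994 did not pass under it (limma, adjusted p = 0.426, 0.109 and 0.17). Their log2 fold changes hardly moved, to 3.03 ± 0.79, -3.07 ± 0.51 and -2.44 ± 0.45, and the calls ended because the SE grew.

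The next question was what glorin adds to starvation at the same time point. At 2 h 10 genes rose and 3 fell with glorin in the fit without the block. There 409 of 10222 genes had an unadjusted p under 0.05 (limma), less than the share of 0.05 due if no gene differed. This fit leaves the experiment difference in its error, so the small count says little about how many genes changed with glorin. PPL_05354 rose from 17.4 ± 7.13 to 988 ± 217 RPKM (SD, n = 2), 56.9-fold, with 486 and 219 reads without glorin and 24704 and 15618 with it. PPL_05833 rose from 3.44 ± 0.0834 to 72 ± 21.6 RPKM, 20.9-fold. PPL_04307 fell 5.72-fold, from 1636 ± 238 to 286 ± 65.2 RPKM, and PPL_08935 fell 5.51-fold, from 88 ± 8.16 to 16 ± 0.43 RPKM. Growing cells held 14.6 ± 9.39 RPKM of PPL_05354 and 13.4 ± 2.4 RPKM of PPL_04307.

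The log2 fold changes with glorin at 2 h were 5.79 ± 0.52 for PPL_05354, 4.01 ± 0.36 for PPL_05833 and -2.39 ± 0.2 for PPL_08935 (limma, adjusted p = 0.0153 for each), and -2.52 ± 0.25 for PPL_04307 (adjusted p = 0.0217). In experiment 1 and experiment 2 the change of PPL_05354 was 5.61 and 5.97. With the block 467 genes rose and 1028 fell, and with block and median-ratio scaling 701 rose and 818 fell. The 4 named genes passed with the block (limma, adjusted p = 1.86e-07 for PPL_05354, 5.98e-07 for PPL_05833 and PPL_04307, and 1.39e-06 for PPL_08935). In both experiments 112 genes were 2-fold higher with glorin and 92 were 2-fold lower, and 1 moved in opposite directions. Leaving out any 1 library ended the calls of the 4 named genes, in fits that do not keep the pairing. The log2 fold changes in them were 5.38 to 6.20 for PPL_05354 and 3.70 to 4.31 for PPL_05833. They were -2.76 to -2.29 for PPL_04307 and -2.48 to -2.29 for PPL_08935. The fit on these 2 groups alone gave 0 genes. With median-ratio scaling 44 genes passed but PPL_05354, PPL_04307 and PPL_08935 did not (limma, adjusted p = 0.0766, 0.0807 and 0.271), nor did PPL_08935 with quantile normalization (adjusted p = 0.0955). Under median-ratio scaling their log2 fold changes were 5.87 ± 0.999, -2.42 ± 0.42 and -2.28 ± 0.59, and PPL_08935 changed by -2.35 ± 0.45 with quantile normalization, so the folds stayed and the SE grew.

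At 3 h 3 genes rose and 7 fell with glorin in the fit without the block. Here too the small count says little, as 224 of 10222 genes had an unadjusted p under 0.05 (limma). That is less than the share of 0.05 due if no gene differed. PPL_05354 rose again, from 15.8 ± 3.97 to 1336 ± 490 RPKM (SD, n = 2), 84.5-fold, and PPL_00117 rose from 101.5 ± 3.78 to 703 ± 125 RPKM, 6.92-fold. PPL_03638 fell 10.9-fold, from 765 ± 94.8 to 70 ± 3.89 RPKM, and PPL_07203 fell 11.4-fold, from 127 ± 30.9 to 11.1 ± 0.946 RPKM. Growing cells held 18.1 ± 2.58 RPKM of PPL_03638 and 10.1 ± 0.812 RPKM of PPL_07203.

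The log2 fold changes at 3 h were 6.28 ± 0.52 for PPL_05354 (limma, adjusted p = 0.0131), 2.77 ± 0.29 for PPL_00117 (adjusted p = 0.0426), -3.43 ± 0.23 for PPL_03638 (adjusted p = 0.0108) and -3.38 ± 0.28 for PPL_07203 (adjusted p = 0.0131). With the block 209 genes rose and 687 fell, with block and median-ratio scaling 362 rose and 439 fell, and with median-ratio scaling alone 6 rose and 7 fell. The median log2 fold change over all genes was -0.133 in the deposited values and -0.003 after scaling. All 4 named genes passed with the block (limma, adjusted p = 1.68e-07 for PPL_05354, 9.72e-06 for PPL_00117, 2.48e-07 for PPL_03638 and 3.56e-06 for PPL_07203). None of the 4 named genes passed under median-ratio scaling alone (limma, adjusted p = 0.0923 for PPL_05354, 0.418 for PPL_00117, 0.0696 for PPL_03638 and 0.0659 for PPL_07203), and PPL_05354 and PPL_00117 did not pass with quantile normalization (adjusted p = 0.0584 and 0.112). The folds stayed and the SE grew: under median-ratio scaling they were 6.42 ± 0.999, 2.92 ± 0.76, -3.28 ± 0.45 and -3.23 ± 0.43 in that order, and with quantile normalization 6.36 ± 0.84 and 2.85 ± 0.48. The genes called with the block had a median coding length of 1857 nucleotides where they rose and 867 where they fell, against 1302 for all tested genes. In both experiments 41 genes were 2-fold higher and 125 were 2-fold lower. No gene passed with any library of these groups left out (0 each), in fits that break the pairing. The log2 fold changes in them were 5.90 to 6.67 for PPL_05354, 2.59 to 2.95 for PPL_00117, -3.55 to -3.30 for PPL_03638 and -3.63 to -3.13 for PPL_07203.

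Averaged over both times, 10 genes rose and 7 fell with glorin in the fit without the block. This count is limited in the same way, with 492 of 10222 genes at an unadjusted p under 0.05 (limma). PPL_05354 changed by 6.04 ± 0.28 on the log2 scale (limma, adjusted p = 0.000483) and PPL_09347 by 4.08 ± 0.38 (adjusted p = 0.0101). PPL_09347 had 1 to 4 reads in the starving libraries without glorin and 100 to 268 reads in those with it. PPL_02260 changed by -2.47 ± 0.26 (adjusted p = 0.0161) and PPL_05902 by -2.38 ± 0.21 (adjusted p = 0.00891). PPL_02260 went from 205 ± 27 to 46.6 ± 19.6 RPKM at 2 h and from 242 ± 60.5 to 34.3 ± 4.75 RPKM at 3 h (SD, n = 2). With the block 268 genes rose and 936 fell, and with block and median-ratio scaling 498 rose and 556 fell. Quantile normalization without the block gave 32 rises and 37 falls, and median-ratio scaling 19 and 25. Leaving out 1 library gave 3 to 11 changed genes, and PPL_09347, PPL_02260 and PPL_05902 each lost their call in several of these fits, with adjusted p up to 0.072, 0.102 and 0.0677 (limma). These fits break the pairing, and the log2 fold changes in them were 3.82 to 4.33, -2.70 to -2.31 and -2.47 to -2.29. With the block the adjusted p was 2.34e-05, 0.00015 and 1.35e-05 (limma).

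Whether the glorin difference itself differed between 2 h and 3 h was tested by the interaction term. By limma without the block 0 genes passed, and voom without the block also gave 0. Of 10222 genes 124 had an unadjusted p under 0.05, less than the share of 0.05 due if no gene differed. Both fits leave the experiment difference in their error, so their 0 calls say little about whether the glorin difference changed with time. With the block 1879 genes had an unadjusted p under 0.05 (limma). The genes named for this contrast did not pass (limma, adjusted p = 0.782 for each), and all 10 passed with the experiment as a block. Among them PPL_05833 differed by -3.31 ± 0.5 between the times, with 72 ± 21.6 RPKM at 2 h and 13 ± 2.91 RPKM at 3 h with glorin, against 3.44 ± 0.0834 and 7.65 ± 1.53 RPKM without (SD, n = 2). PPL_09088 differed by 1.74 ± 0.31. With the block their adjusted p was 0.000114 and 0.00132 (limma). With the block 137 genes had a higher glorin difference at 3 h and 227 a lower one, and with block and median-ratio scaling these were 217 and 260.

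Glorin differences at 2 h and at 3 h, which share no library, correlated across 10222 genes at Pearson r = 0.43 and Spearman rho = 0.26. Within the experiments r was 0.24 and 0.42, and with the times taken from different experiments it was 0.4 both ways. All 3 genes that rose at 3 h had also risen at 2 h. With the block 104 genes rose at both times against 9.5 expected for independent lists, and 282 fell at both against 69.1 expected. Both lists use the same error per gene, which favours overlap in either direction. In opposite directions, 20 rose at 2 h and fell at 3 h (31.4 expected), and 15 fell at 2 h and rose at 3 h (21 expected). Leaving out 1 library, which unbalances the experiments between the groups compared, gave r from 0.102 (without the 2 h library of experiment 2) to 0.578 (without that of experiment 1).

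The last comparison set glorin against starvation. Of the 3 genes that fell with glorin at 2 h, 3 had risen after 3 h of starvation, and of the 7 that fell with glorin at 3 h, 5 had risen after 2 h of starvation. Of the 10 that rose at 2 h, 2 rose after 3 h of starvation and 0 fell (0.3 expected of each for independent lists). These numbers are too small to give a direction. With the block, 698 of the 1028 genes that fell with glorin at 2 h rose after 3 h of starvation (436.3 expected for independent lists), and 137 of the 467 that rose with glorin fell after starvation (81.8 expected). For glorin at 3 h and starvation at 2 h these were 411 of 687 (311.3 expected) and 73 of 209 (36.4 expected). Same-direction overlaps with the block were 187 of 467 genes raised by both (198.2 expected) and 159 of 1028 lowered by both (180 expected) for glorin at 2 h. For glorin at 3 h they were 86 of 209 (94.7 expected) and 134 of 687 (119.6 expected). With block and median-ratio scaling, 463 of 818 (195.1 expected) and 238 of 439 (107 expected) of the glorin-lowered genes had risen with starvation, and 278 of 701 (201.6 expected) and 162 of 362 (113.6 expected) of the glorin-raised genes had fallen. Same-direction overlaps were then 159 of 701 (167.2 expected) and 97 of 362 (88.2 expected) raised by both, and 156 of 818 (235.3 expected) and 95 of 439 (137.8 expected) lowered by both.

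Across all 10222 genes the glorin difference at 2 h correlated with the starvation difference at 3 h at r = -0.19 (rho = -0.18), and the glorin difference at 3 h with the starvation difference at 2 h at r = -0.16 (rho = -0.09). Within experiments r was -0.09 and -0.19 for the first pair and -0.14 and -0.17 for the second. With the contrasts taken from different experiments r was -0.24 and -0.18, and -0.13 and -0.15. At the same time point, again from different experiments so that no library was shared, r was -0.29 and -0.25 at 2 h and -0.09 and -0.13 at 3 h. There the starving group without glorin enters both contrasts with opposite signs, which favours a negative r. Genes are not independent replicates, so no p is given.

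**Figure D3:**
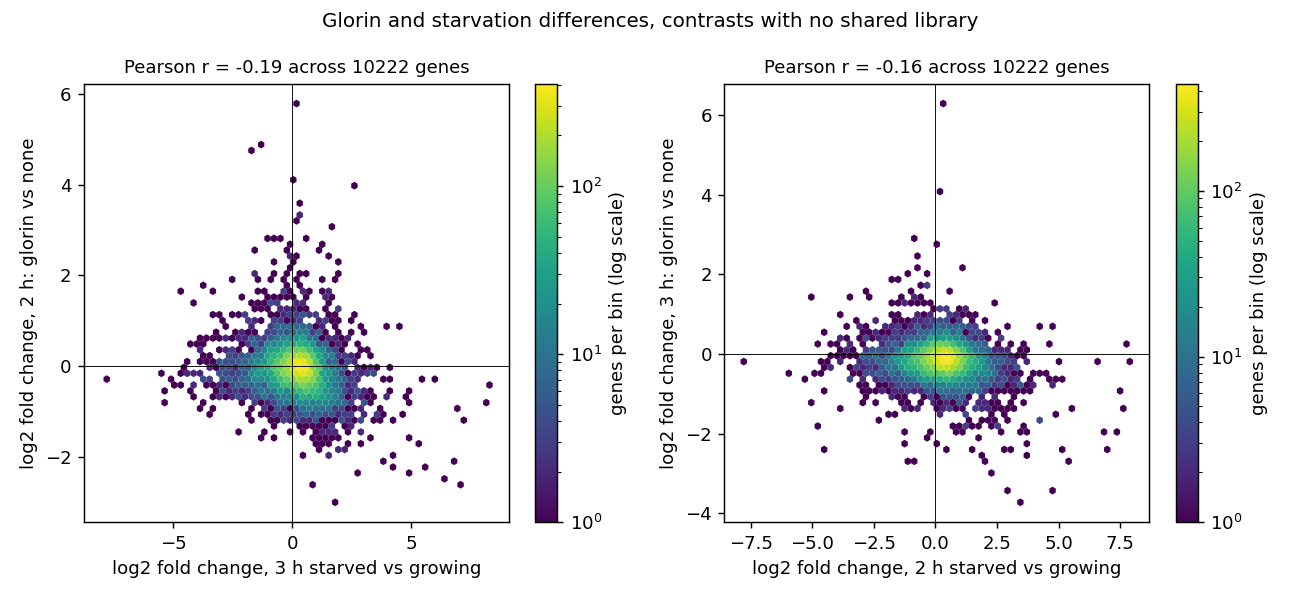
Log2 fold change with glorin (y axis) against log2 fold change with starvation (x axis) for 10222 genes, for glorin at 2 h and starvation at 3 h (left) and for glorin at 3 h and starvation at 2 h (right), with colour for the number of genes per hexagon on a log scale. Pearson r was -0.19 on the left and -0.16 on the right.

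Cells starved with glorin were also set against growing cells. At 2 h 287 genes rose and 296 fell, and at 3 h 313 rose and 313 fell. PPL_02774 stood at 218 ± 42.2 RPKM and 450.5 ± 39.7 RPKM (SD, n = 2), and PPL_07847 at 0.387 ± 0.135 and 0.377 ± 0.219 RPKM. PPL_06963 fell from 219 ± 183 RPKM in growing cells to 1.48 ± 1.32 RPKM at 3 h, a log2 fold change of -6.28 ± 0.9 (limma, adjusted p = 0.00942). That call ended without growing cells of experiment 2 (log2 fold change -5.30, adjusted p = 0.0625) and without the 3 h glorin library of experiment 1 (-5.71, adjusted p = 0.0834), and held with the block (adjusted p = 3.16e-08; limma). With the block 4300 rose and 1845 fell at 2 h, and 3462 rose and 2232 fell at 3 h. With block and median-ratio scaling these were 2537 and 2908, and 2643 and 3067. Leaving out 1 library gave 172 to 242 changed genes at 2 h and 160 to 234 at 3 h.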

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

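Tests chosen after the result was seen were the share of genes that differ between experiments after scaling, the correlations of glorin with starvation at the same time point, the use of the planned correlations across experiments against a shared batch, and both tests of the excess of higher genes after starvation.

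The glorin difference differed between 2 h and 3 h for 364 genes by the interaction term with the experiment as a block, against 0 genes without the block. Of these, 233 (64%) had glorin differences of opposite sign at the times, against 39.2% of all tested genes, although choosing genes for a large difference between the times favours opposite signs, and 35 of the 233 were called at both times with the block. Of the rest, 92 had the same sign and a larger size at 2 h, and 39 had the same sign and a larger size at 3 h.

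Libraries of experiment 1 and experiment 2 differed in the same way in all 5 groups, with a mean correlation of deviations of 0.88. A few abundant genes taking most of the reads would shift all other genes by 1 factor per library, yet 73.8% of genes still differed between experiments after median-ratio scaling. Removing the trend on coding length left the mean correlation at 0.88. Had the experiments stood at different points of the change from 0 h to 2 h, their glorin libraries would differ along it. That difference had r = 0.02 with the change. The glorin libraries are from 2 h and 3 h, and a shift along the step between those times was not tested. The labels do not say how the experiments differed, so culture, day and library batch stay open. No biological explanation other than the point in the change from 0 h to 2 h was tested.

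Starvation and glorin differences were weakly and negatively correlated across genes (r = -0.19 and -0.16 for contrasts that share no library). Single genes need not follow this. The mean of PPL_02774 was lower with glorin at 2 h (218 against 284 RPKM) and higher at 3 h (450.5 against 371 RPKM). The drop at 2 h came from experiment 1 (188.4 against 320.9 RPKM) and was absent in experiment 2 (248.1 against 246.7 RPKM). The rise at 3 h was seen in both (478.5 against 361.1 and 422.4 against 380.6 RPKM). An offset shared by the libraries of an experiment cancels within each contrast, so it could not have given a negative r. The r taken across experiments therefore do not test such a batch, and show only that the sign held between experiments. The highest was -0.13 among the 4 pairings of glorin at one time with starvation at the other, and -0.09 among those at the same time. Pairs at the same time share the starving group without glorin with opposite signs, which favours a negative r. Of the 2 r between contrasts that share no group, the higher was -0.2 after the trend on coding length was removed, which argues against length bias as the whole cause. Among genes with a mean of at least 10 RPKM the higher was -0.17. Noise of genes with few reads is separate between contrasts that share no library. It would weaken r and not make it negative, so that test could not have found it as the cause. A hypothesis is that glorin may hold back part of the starvation response, although r is small. This hypothesis was found on these data, and no test run here could decide it.

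In the fit with the block more genes were higher than lower after starvation. A loss of read share by a few abundant genes could raise all others. The test tried first, the share of higher genes among those called at 2 h after median-ratio scaling, gave 43.7% and decides nothing, since that scaling centres the genes. In a further test, chosen once that outcome was known, the share of reads lost by the 100 genes with most reads in growing cells accounted for 51.5% of the median rise of the others at 2 h, with 45.8% and 57.1% in the experiments, on either side of the bound of 50% set for it. The mean passes that bound as computed, but whether it would on a common scale was not tested. The requirement that both experiments pass it was added after the values were seen. At 3 h, for which no bound was set, the shares were 50% and 50.3%. A rise of the other genes would also lower the share of the abundant ones, since shares are parts of the same total. Passing the bound could therefore not have told cause from result. The explanation stays open, and any part of the rise that it leaves was not explained.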

How the results depend on the processing

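The tests chosen after the result was seen were voom on recovered reads and the block combined with voom or with median-ratio scaling. The planned count test on recovered reads was left out by choice, with voom on those reads run in its place. The planned camera tests of lists were not run, since 0 lists matched the identifiers. In every list of counts below the order is 2 h and 3 h of starvation against growing cells, glorin at 2 h, glorin at 3 h, 3 h against 2 h, glorin at 2 h and at 3 h against growing cells, the interaction, and glorin over both times.

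Counts of changed genes were 676, 573, 13, 10, 5, 583, 626, 0 and 17. With the replicate block they were 6412, 6128, 1495, 896, 789, 6145, 5694, 364 and 1204. All genes called without the block were also called with it. With block and voom they were 6636, 6420, 1870, 1138, 1110, 6470, 5960, 590 and 1423, and with block and median-ratio scaling 5699, 5378, 1519, 801, 858, 5445, 5710, 477 and 1054. Quantile normalization gave 1596, 1443, 48, 13, 0, 1374, 1506, 0 and 69. Median-ratio scaling gave 1614, 1379, 44, 13, 8, 1349, 1442, 1 and 44. A fit on the compared groups alone gave 7, 39, 0, 0, 0, 33 and 18 for the first 7 comparisons, with 2 residual degrees of freedom. For glorin at 3 h a pseudocount of 5 gave 16 and no filter on low values gave 4. Other pseudocounts and filters, a 2-fold minimum and voom without the block kept each count within 1.5 times. Beyond the construction of each alternative the cause was not tested.

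With each library left out in turn, the counts ran from 127 to 191, 140 to 197, 1 to 2, 0 to 0, 0 to 0, 172 to 242, 160 to 234, 0 to 0 and 3 to 11, the lone library being assumed to vary like the other groups. The correlation of the glorin differences ran from 0.102 to 0.578, that of glorin at 2 h with starvation at 3 h from -0.246 to -0.107, and that of glorin at 3 h with starvation at 2 h from -0.266 to -0.031. These fits unbalance the experiments between the groups compared, so the experiment difference enters them. With experiment 1 set against experiment 2 the last was -0.127. No sign changed. Named genes that passed kept their direction throughout. Their call was kept in 69 and lost in 71 of 140 fits with a library left out, and kept in 137 and lost in 18 of 155 fits under other settings.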

Other observations

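Tests chosen after the result was seen were the correlations of the glorin differences with the later step of starvation, and the counts of genes crossing from under 1 to at least 10 RPKM or back. The genes picked out in the next paragraph come from the rule for named genes, but their profiles were picked after they were seen.

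The named genes followed different courses over time. PPL_04573 held 456 ± 49.4 RPKM in growing cells, 36.1 ± 4.07 RPKM after 2 h and 293 ± 75.2 RPKM after 3 h (SD, n = 2), and 388 ± 57.9 RPKM after 3 h with glorin. PPL_05902 held 0.672 ± 0.0928 RPKM in growing cells, 12.2 ± 0.583 RPKM after 2 h and 47.1 ± 10.2 RPKM after 3 h, but 1.53 ± 0.181 and 8.21 ± 0.238 RPKM with glorin. PPL_00117 was near 100 RPKM in growing and starving cells (87.1 ± 18.8, 93.8 ± 32.8 and 101.5 ± 3.78 RPKM) and at 1137 ± 44 and 703 ± 125 RPKM with glorin.

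From growing cells to 2 h of starvation 11 genes went from under 1 to at least 10 RPKM in both libraries and 7 went the other way, and at 3 h these were 8 and 5. With glorin 2 genes crossed upward at 2 h and 1 at 3 h, and 0 crossed downward at either time. The difference in median coding length between genes that fell and rose with glorin at 3 h (867 and 1857 nucleotides with the block) was not seen at 2 h (1372.5 and 1377), and whether it bears on the calls at 3 h was not tested. In all libraries 188 entries of 71 to 83 nucleotides held 0 to 2 reads together.

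The average glorin difference over both times was compared with other splits of the 8 starving libraries into 4 and 4. Of 34 splits that could be fitted, 2 gave at least as many genes as the 17 of the real split, the real one included. The other was the split by experiment, with 7647 genes, far more than the real count, which points to a structure of the samples, so this count does not bear on chance. The remaining splits gave 0 genes. Among the 8 splits that part all 4 pairs of the same time and experiment, the real split gave 1204 genes with the block and the highest other gave 1. These are too few for a share under 0.05, the smallest share possible being 0.125.

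Genes with consecutive numbers were slightly more alike than other pairs. Over 8530 pairs the median correlation over the 10 libraries, centred per experiment, was 0.254, above the highest median of 1000 shuffles (0.195). At distances of 2, 3, 5, 10 and 100 numbers it was 0.188, 0.19, 0.174, 0.15 and 0.176, none of them above that highest shuffle. Neighbouring genes may share part of their response. Whether the numbers follow the order along the chromosomes is not given in the files, and reads shared between near-identical neighbours were not tested.

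A further hypothesis was that glorin moves the cells along the path they take between 2 h and 3 h. The glorin difference at 2 h correlated with the change from 2 h to 3 h at r = 0.15 and 0.17 with the contrasts taken from different experiments. The lower, 0.15, lies between the bounds set for the test (0.3 for and 0.1 against). For the glorin difference at 3 h, for which no bound was set, r with the same change was 0.1 and 0.05. At 2 h both contrasts subtract the 2 h group without glorin, so whatever repeats in that group raises r even across experiments. At 3 h the 3 h group without glorin enters with opposite signs, which lowers r. These r therefore cannot decide the hypothesis or be compared between the times. It may hold in part at 2 h or not at all.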
